A study of Arabidopsis thaliana with 6 samples.

How the data were processed

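The study sequenced messenger RNA from whole seedlings of wild type and gbpl3, 3 libraries per genotype, as strand-specific Illumina libraries read in pairs, per the labels' protocols. The authors deposited a table of raw counts per gene and a table of FPKM values. Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.6.1p1 and the TAIR10 build were used. The strand setting of the counting, its treatment of reads that match several genes, and the read filters are not given in the sources used here. Deposited counts are whole numbers with different totals per library and were taken as raw. The deposited FPKM values equal the counts divided by a gene length and the library's total count, as recomputed from both files, and the implied length agreed between libraries within 0.00068 bases. For genes with 1 transcript in the reference that length equalled the union of exons, within 0.5 bases, in 99.0% of 14982 genes. For genes with several transcripts it did so in 1.72% of 10649 genes, and in 77.2% it equalled the sum of all distinct exons, so overlapping exons counted repeatedly and the median length was 1.59 times the exon union. FPKM levels of such genes are therefore too low relative to other genes, while ratios between libraries are unaffected.

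Genotype and replicate number were taken from sample titles. The mutant libraries carry numbers 1 to 3, which were read as replicates because the design text speaks of triplicates. Columns were matched to samples by name, and no column of sample values was left over. GBPL3 was taken to be AT5G46070, an assignment made from background knowledge, since the annotation names the gene only as a guanylate-binding family protein. GBPL1 (AT1G03830) and GBPL2 (AT2G38840) were assigned in the same way. Other gene names and all coordinates come from the TAIR10.1 reference, which held 99.1% of the 32833 gene identifiers. Where the reference gave no symbol, the name in the gene lists was used if there was one. Library pairs within a genotype had a chi-square per degree of freedom over genes of 4.97 to 14.4. Sampling noise alone gives about 1, so none was a duplicate. Pairs between genotypes ran from 9.98 to 34.6. The 14.4 of wild-type replicates 1 and 2 thus exceeded some pairs between genotypes.

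Genes were kept with edgeR's filterByExpr, which left 20677. Libraries were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. A size filter of 2-fold was applied to the estimates. For genes without a count in wild type a floor of 3 counts over the group replaced the count, and for 1 to 3 counts an exact 95% conditional interval was computed. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated and with fry, which tests whether a list's genes move on balance in 1 direction.

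The 25 lists covered the nuclear pore complex, nuclear lamina and envelope, salicylic acid, pattern-triggered immunity, jasmonate, abscisic acid, heat shock, photosynthesis, mitosis, DNA replication, DNA damage, auxin, flavonoids, glucosinolates, flowering, morning and evening clock genes, root hairs, root tissues, seed storage, senescence, ribosome biogenesis, iron, phosphate and DNA methylation. They held 500 members, and the reference gave the listed symbol for 460. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took GBPL3, GBPL1 and GBPL2, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between genotypes. It added the 6 most abundant genes called with at least a 2-fold change, and up to 4 members with the smallest adjusted p from each list that was shifted or had at least 3 called members. Further members named in the text were chosen after their values were seen: FRK1, CYP71A13, RHD6, RSL4, FER4, FRU, IRT1, FRO2, NUA, PR1, RAB18, LTI65, SESA2, CRU3, DREB2A, MYB12, GMI1, RAV2, MET1 and PRR5, the family examples AT4G36430, PRX52, AT3G01190, DOX1, EXT10, EXT12 and AT4G12545, and AT5G46060 beside GBPL3.

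Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean of at least 1 FPKM or no filter. Offsets for exon length and GC content were added after seeing the data. Of the tests of other explanations, those on root tissue, hair cells, seed RNA, length and GC content, abundant genes and the GBPL3 region were reworded after a run of their own results. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 72% and 95% and called 17 unchanged genes, DESeq2 recovered 68% and 94%, and limma on log2(FPKM + 1) 58% and 89%. These simulations used the means and library sizes of this comparison.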

Results

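Messenger RNA was sequenced from whole 7-day-old Arabidopsis thaliana seedlings of 2 genotypes, the Col-0 wild type and a gbpl3 mutant, with 3 libraries each. GBPL3 is a guanylate-binding-like protein that the series' title places in the basket of the nuclear pore. Seedlings were untreated and grew on half-strength MS medium with 1% sucrose, and about 50 mg of tissue was used per extraction. CPM are counts scaled to the size of the library. The count table held 32833 genes, of which 25796 had at least 1 count. Total counts were 11061554, 12104120 and 9530643 in wild-type replicates 1 to 3 and 10836165, 12911891 and 11312668 in gbpl3 replicates 1 to 3. In the smallest library, 3 counts correspond to 0.315 CPM. Levels below are normalised CPM as mean ± SD with n = 3 per genotype, and each adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 20677 genes. The labels do not say whether the libraries of a genotype came from separate cultures, so p-values measure the spread between these samples, which may be technical.

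GBPL3 itself (AT5G46070) was lower in every gbpl3 library than in every wild-type library. Its level was 67.6 ± 1.46 CPM in wild type and 16.4 ± 2.12 CPM in gbpl3, 4.11-fold lower (log2 fold change -2.04, SE 0.12, adjusted p = 5.11e-09). Raw counts were 790, 827 and 646 in wild type and 156, 243 and 168 in gbpl3. In the TAIR10.1 annotation the gene lies on chromosome 5 from 18683319 to 18688822 and has 14 exons. Of its relatives, GBPL1 (AT1G03830) fell from 20.7 ± 2.44 to 14.2 ± 0.441 CPM (log2 fold change -0.54, SE 0.15, adjusted p = 0.0218). That call ended without wild-type replicate 2 (adjusted p = 0.0682), gbpl3 replicate 1 (0.0824) or gbpl3 replicate 3 (0.0918). GBPL2 (AT2G38840) had a log2 fold change of 0.17, which did not pass the test (adjusted p = 0.52).

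**Figure D1:**
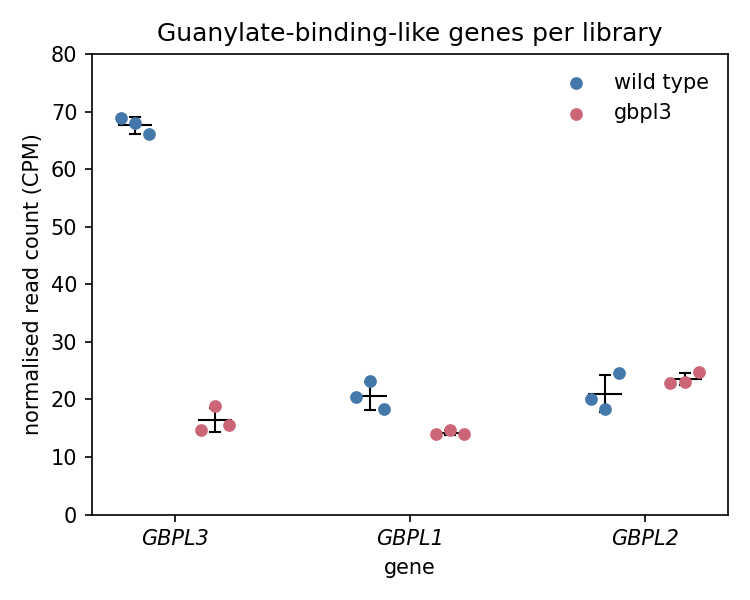
Normalised read counts (CPM, linear axis from 0) of GBPL3, GBPL1 and GBPL2 in each of 3 wild-type and 3 gbpl3 libraries, with points for libraries, horizontal bars for means and error bars for the SD. GBPL3 averages 67.6 CPM in wild type and 16.4 CPM in gbpl3.

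The comparison of the mutant with wild type asks which transcripts differ when GBPL3 expression is reduced. In gbpl3 seedlings 1253 genes were higher and 969 lower, 10.7% of the genes tested, and 425 were at least 2-fold higher against 147 at least 2-fold lower. The largest rises included 2 genes of the peroxidase superfamily. AT2G18150 rose from 0.243 ± 0.264 to 48.4 ± 3.91 CPM (log2 fold change 7.59, SE 0.30, adjusted p = 1.69e-11), with log2 fold changes of 8.88 without wild-type replicate 1 and 6.96 without wild-type replicate 2. AT1G49570 had 2 counts over the wild-type libraries and 105, 102 and 99 in the gbpl3 libraries, a ratio of 143 with an exact 95% counting interval of 39.2 to 1183. AT5G52390, a PAR1 protein gene, had no count in wild type and 31, 34 and 41 counts in gbpl3, at least 33.0-fold higher against a floor of 3 counts over the group. FLA6, a fasciclin-like arabinogalactan gene, had 2 wild-type counts and a ratio of 69.9 (interval 19.0 to 583), and its log2 fold change of 5.93 was 8.66 without wild-type replicate 3. The cupin gene AT4G36700 and AT5G36150 (PEN3), a putative pentacyclic triterpene synthase gene, had 1 wild-type count each and ratios of 125 (22.05 to 4972) and 98.9 (17.36 to 3941), with log2 fold changes of 6.62 and 6.24 that were 8.55 and 8.17 without wild-type replicate 3. The late embryogenesis genes AT3G53040 and M17 had 1 and 3 wild-type counts and ratios of 80.2 (14.02 to 3204) and 61.5 (20.8 to 301). For AT3G53040 the log2 fold change of 5.95 was 7.88 without wild-type replicate 3 and 5.25 without gbpl3 replicate 3, and for M17 the value of 5.87 was 6.65 without wild-type replicate 2 and 4.64 without gbpl3 replicate 3. EPR1, an extensin gene, had 23, 294 and 145 counts in gbpl3 (log2 fold change 6.33, 7.79 without wild-type replicate 2 and 5.61 without gbpl3 replicate 2). CRA1, also among the 10 largest rises, is described with the seed genes. Seed-like material that differs between samples, left open below, may also bear on AT3G53040 and M17 and was not tested for them.

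The largest falls were those of AT5G33355, a defensin-like gene, from 11.1 ± 2.17 to 0.108 ± 0.117 CPM, and of AT4G15670, a thioredoxin superfamily gene, from 4.07 ± 0.86 to 0.0516 ± 0.0893 CPM. Their log2 fold changes were -6.45 and -5.88, and without gbpl3 replicate 2 they were -7.57 and -8.47. AT4G15680, a neighbour of AT4G15670 with a related sequence, fell 6.25-fold, and reads shared between such copies make their separate levels uncertain. TIP2;3, which encodes a tonoplast aquaporin, fell from 87.6 ± 33.2 to 4.61 ± 1.06 CPM (adjusted p = 6.17e-09). AGL17, ELIP1, PGL4, AT4G22463, AT1G64590 and XTH21 completed the 10 largest falls, by 5.74-fold to 7.60-fold. Without gbpl3 replicate 1 the log2 fold change of PGL4 was -4.02 instead of -2.89. AT4G22463 had 166 counts over all libraries and overlaps AT4G22460, which had 152, so its fall is uncertain. Among abundant genes, the cell wall extensin gene EXT4 rose from 280 ± 43.3 to 724 ± 71.4 CPM and MLP34 fell from 423 ± 3.55 to 187 ± 25.2 CPM. CYP81F4 fell 2.11-fold and AT4G37409 2.16-fold, but these genes overlap on opposite strands and their counts, 17087 and 16067 over the 6 libraries, cannot be assigned with certainty. AT4G11320 fell 2.01-fold and BBD1 rose 2.07-fold.

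Of the called genes, 2165 had all gbpl3 libraries beyond all wild-type libraries, as had 28.1% of all tested genes, where chance gives 10%. The number of calls changed when single libraries were left out. A fit with fewer libraries has less power, so a call can end although its estimate hardly moves. An ended call, here and in the other paragraphs, therefore does not by itself show that the omitted library carried the difference. Without wild-type replicate 2 the calls rose to 1443 higher and 1238 lower. Without wild-type replicate 1, 609 genes were lower, and without wild-type replicate 3, 814 were higher and 563 lower. Without gbpl3 replicate 1, 661 were higher and 410 lower, and without gbpl3 replicate 3, 629 were higher and 320 lower.

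Of 25 gene lists, 14 were shifted by camera with a preset correlation of 0.01 between genes, 9 upward and 5 downward. No list was shifted when the correlation was estimated from the libraries, and camera shifted up to 13 lists when the 6 libraries were split in ways that mix the genotypes. By fry, 7 lists were shifted (adjusted p = 0.0243 to 0.032): pattern-triggered immunity, jasmonate, mitosis, DNA replication, root hairs, seed storage and senescence. Fry was not run on the mixed splits. A mixed split still keeps part of the genotype difference between its groups, so those 13 lists do not measure chance alone. Since no list was shifted with an estimated correlation, the list tests only rank the lists here, and the calls of single members carry the evidence per gene.

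**Figure D2:**
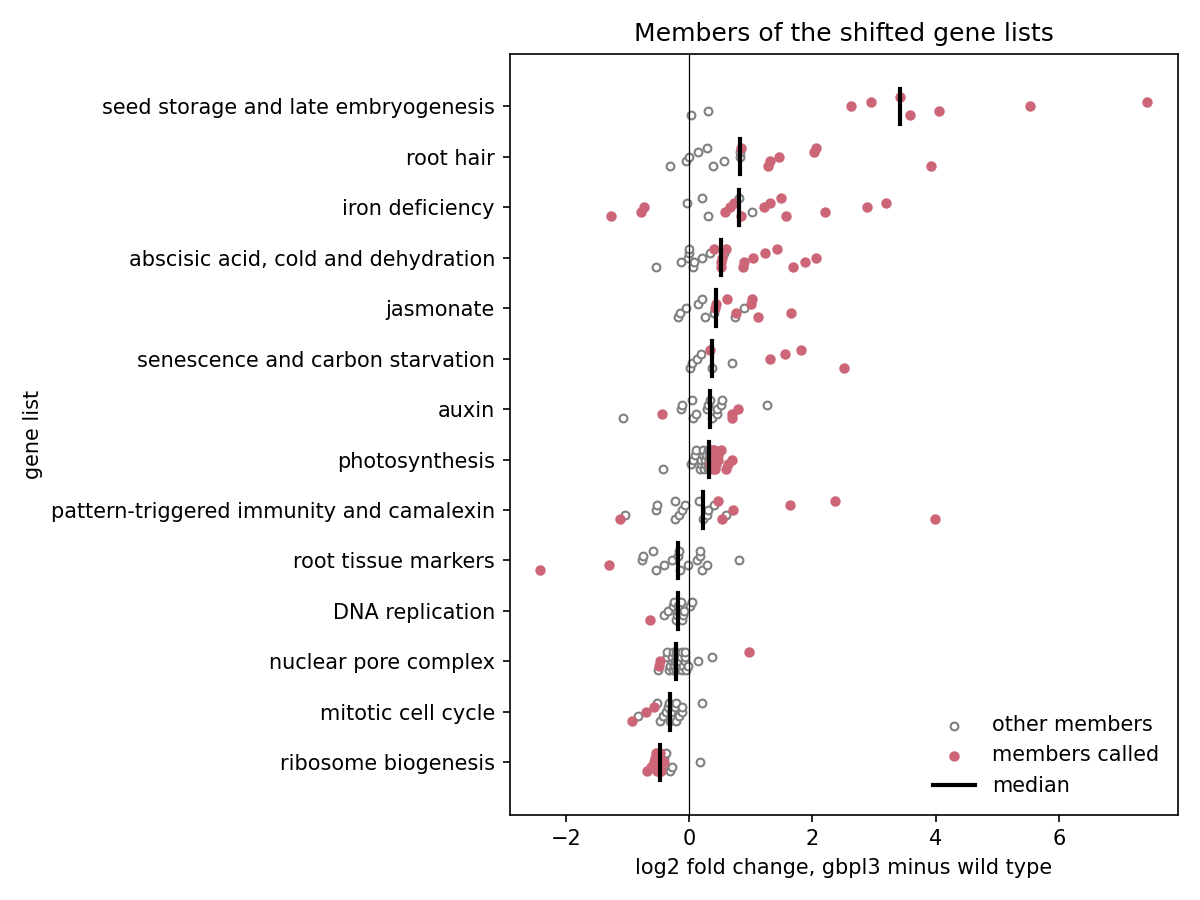
Log2 fold changes (gbpl3 minus wild type) of the tested members of the 14 lists shifted by camera with the preset correlation, with filled points for members with an adjusted p under 0.05, open points for other members and black bars for list medians. Medians run from -0.47 for ribosome biogenesis to 3.42 for seed storage.

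Of the root hair genes, 7 of 16 were higher in gbpl3, none lower and 9 not called. PRP1 and PRP3, proline-rich cell wall protein genes of root hairs, rose from 0.947 ± 0.54 to 14.7 ± 3.31 CPM and from 14.4 ± 2.11 to 60.3 ± 14.7 CPM. RHS19, a root hair peroxidase gene, rose 4.08-fold and LRX1, an extensin-like wall protein gene, 2.47-fold. RHD6 and RSL4, regulators of hair formation, stood at log2 fold changes of 0.00 and 0.28 and were not called (adjusted p = 0.997 and 0.729). The list's median log2 fold change was 0.82 (camera adjusted p = 2.92e-08, and adjusted p = 0.223 with an estimated correlation), and 10 members were higher when adjusted over the list alone. Root tissue markers of other cell types had a median of -0.17, with 2 of 18 members down and none up (camera adjusted p = 0.0155, and adjusted p = 0.44 with an estimated correlation). RCI3 fell from 67.7 ± 8.93 to 27.6 ± 6.05 CPM and CASP5, a Casparian strip gene, from 2.81 ± 0.79 to 0.503 ± 0.333 CPM, while 1 member was higher and 4 lower when adjusted over the list alone. Without wild-type replicate 2 the list's adjusted p was 0.06 and without gbpl3 replicate 3 it was 0.154, and the CASP5 call also ended without gbpl3 replicate 3 (adjusted p = 0.0513). CASP5, with 113 counts, overlaps AT5G15300 on the opposite strand, with 152, and its log2 fold change of -2.42 was -3.06 without gbpl3 replicate 2.

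Seed storage and late embryogenesis genes had the largest list median, 3.42, with 7 of 9 tested members up and none down, as also when adjusted over the list alone. The list held 20 members, and the others did not pass the count filter. With few wild-type counts, a member passes mainly when it is high in gbpl3, so the median and this share are selected upward. CRA1, a 12S cruciferin storage protein gene, had 2, 0 and 9 counts in wild type and 138, 452 and 1385 in gbpl3. OLEO1 and OLEO2, which encode oil body oleosins, had 10, 46 and 102 and 42, 62 and 117 counts in gbpl3. PER1, a seed peroxiredoxin gene, rose from 0.594 ± 0.565 to 9.69 ± 7.49 CPM. OLEO1 had 3 wild-type counts and a ratio of 49.1 (16.5 to 241), and both oleosin genes overlap neighbours with 176 and 49 counts. Log2 fold changes of OLEO1 (5.53), OLEO2 (3.58) and PER1 (4.05) were 4.51 without gbpl3 replicate 3 for OLEO1, 2.99 and 4.72 without wild-type replicates 1 and 2 for OLEO2, and 3.45, 4.79 and 3.202 without wild-type replicate 1, wild-type replicate 3 and gbpl3 replicate 3 for PER1. The SD of CRA1 in gbpl3, 61.5 CPM, exceeded its mean of 58.9 CPM, and its log2 fold change of 7.43 was 6.14 without gbpl3 replicate 3, 6.79 without wild-type replicate 2 and 9.27 without wild-type replicate 3. Without gbpl3 replicate 3, 4 members were called (camera adjusted p = 3.62e-07 with all libraries, and adjusted p = 0.223 with an estimated correlation).

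Of the genes of abscisic acid, cold and dehydration responses, 13 of 23 were up, none down and 10 not called, and 13 were up when adjusted over the list alone. KIN2, a cold- and ABA-induced gene, rose from 97.2 ± 30.1 to 228 ± 51.2 CPM, and RD22, a dehydration-induced gene, rose 1.43-fold. Wild-type replicate 2 stood apart from the other wild-type libraries on the second principal component (-42.6 against 28.4 and 10.1) and had the highest wild-type KIN2 level, 127 CPM against 67.1 and 97.3 CPM. Without gbpl3 replicate 3, the library with the most CRA1 counts, the calls of RAB18 and LTI65 ended, with log2 fold changes of 0.83 and 1.39 instead of 1.42 and 2.05 (adjusted p = 0.252 and 0.217). The RAB18 call also ended without wild-type replicate 1 (0.0543), wild-type replicate 3 (0.0984) or gbpl3 replicate 1 (0.0599). The list median was 0.52 (camera adjusted p = 3.94e-07, and adjusted p = 0.326 with an estimated correlation). Members called fell to 6 without wild-type replicate 3, 4 without gbpl3 replicate 1 and 3 without gbpl3 replicate 3. Of the senescence and carbon starvation list, 5 of 11 members were up and none down, and 6 up when adjusted over the list alone. SEN1 rose 2.94-fold and the NAC transcription factor gene NAC6 (AT5G39610, also called ORE1) 2.48-fold (list median 0.38, camera adjusted p = 2.11e-05, and adjusted p = 0.223 with an estimated correlation). Without wild-type replicate 1, gbpl3 replicate 1, gbpl3 replicate 2 or gbpl3 replicate 3, 3 members were called.

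Among pattern-triggered immunity and camalexin genes, 6 of 21 were up and 1 down. The rises were led by the camalexin branch: CYP71A12 rose from 3.68 ± 0.526 to 58.5 ± 3.72 CPM, 15.9-fold (adjusted p = 1.32e-11), and PAD3, whose product makes camalexin, from 2.07 ± 0.437 to 10.7 ± 0.471 CPM, 5.15-fold. CYP71A13, a close sequence relative of CYP71A12, stood at 0.961 ± 0.469 and 2.93 ± 1.07 CPM, and shared reads leave the split between the pair uncertain. WRKY33 rose 1.64-fold and MPK3 1.39-fold, whereas FRK1, a flagellin-induced kinase gene, fell 2.18-fold, a call that ended without wild-type replicate 1 (adjusted p = 0.0818) or gbpl3 replicate 3 (0.0904). The CYP71A13 call ended without any library but wild-type replicate 3 (adjusted p = 0.0501 to 0.179). WRKY33, with 1601 counts, overlaps AT2G38480 on the opposite strand, with 618, which makes its rise uncertain. The list median was 0.23, and 0.0091 without gbpl3 replicate 3 (camera adjusted p = 0.0114, adjusted p = 0.0555 without wild-type replicate 2, and adjusted p = 0.223 with an estimated correlation), with 6 members up and 2 down when adjusted over the list alone. Salicylic acid and systemic resistance genes moved both ways, 3 up and 3 down of 22, and the list was not shifted (median 0.13, camera adjusted p = 0.222). CBP60G rose from 3.08 ± 1.23 to 10.6 ± 2.53 CPM, WRKY53 had a log2 fold change of -0.58, and PR1, the usual salicylic acid marker, had 0 counts in every library. Adjusted over the list alone, 5 members were up and 3 down. Without wild-type replicate 1, wild-type replicate 3 or gbpl3 replicate 2, 1 member was lower, and without gbpl3 replicate 1 or 3 none was. WRKY53, with 1476 counts, overlaps AT4G23800 on the opposite strand, with 6402, which makes its fall uncertain. The WRKY53 call ended without wild-type replicate 1 (adjusted p = 0.09), gbpl3 replicate 1 (0.0767) or gbpl3 replicate 3 (0.0799).

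Of the jasmonate genes, 8 of 17 were up and none down, and 9 up when adjusted over the list alone. They included biosynthesis enzymes, with AOS from 107 ± 6.57 to 164 ± 19.4 CPM and AOC1 from 8.25 ± 1.05 to 16.6 ± 2.99 CPM, and the JAZ repressor gene TIFY7, which rose 2.18-fold. The median was 0.44 (camera adjusted p = 4.0e-06, and adjusted p = 0.223 with an estimated correlation), and 5 members were called without gbpl3 replicate 1. Auxin genes had 3 members up and 1 down of 19, and 6 up and 1 down when adjusted over the list alone. WES1 and DFL1, GH3 enzymes that conjugate auxin, rose 1.74-fold and 1.61-fold, and the efflux carrier gene EIR1 (also called PIN2) fell 1.35-fold, a call that ended without wild-type replicate 3 (adjusted p = 0.1) or gbpl3 replicate 3 (0.184). The median was 0.34 (camera adjusted p = 0.0114, and adjusted p = 0.367 with an estimated correlation), and without either of those libraries 2 members were up and none down.

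In the iron deficiency list 11 of 19 members were up and 3 down. BHLH100 and BHLH101, transcription factor genes induced by low iron, rose from 0.919 ± 0.699 to 8.54 ± 3.45 CPM and from 2.52 ± 0.593 to 11.5 ± 1.73 CPM, and IMA2, an iron-responsive peptide gene, rose 2.81-fold. The members that fell were the ferritin genes FER1, from 117 to 48.3 CPM, and FER4, 1.67-fold, which encode iron storage proteins, and FRU (AT2G28160, also called FIT), a regulator of root iron uptake, 1.72-fold. The FRU call ended without wild-type replicate 3 (adjusted p = 0.0927), gbpl3 replicate 1 (0.0729), gbpl3 replicate 2 (0.0558) or gbpl3 replicate 3 (0.0906). BHLH101, with 478 counts, overlaps AT5G04140 on the opposite strand, with 68917, so stray reads may add to its level. IRT1 and FRO2, which take up iron at the root surface, were not called, at log2 fold changes of -0.03 and 0.21. The median was 0.80 (camera adjusted p = 3.3e-06, and adjusted p = 0.29 with an estimated correlation), with 13 up and 3 down when adjusted over the list alone. BHLH100 had a log2 fold change of 3.18, and 3.87 without wild-type replicate 2. Of the phosphate starvation genes, RNS1 rose 7.78-fold and PPCK1 and SPX1 fell 1.68-fold and 1.97-fold among 15 members, and the list was not shifted (median -0.30, camera adjusted p = 0.221). Adjusted over the list alone, 1 was up and 4 down, and 4 were lower without wild-type replicate 2. PPCK1, with 1638 counts, overlaps AT1G08645 on the opposite strand, with 849, which makes its fall uncertain.

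**Figure D3:**
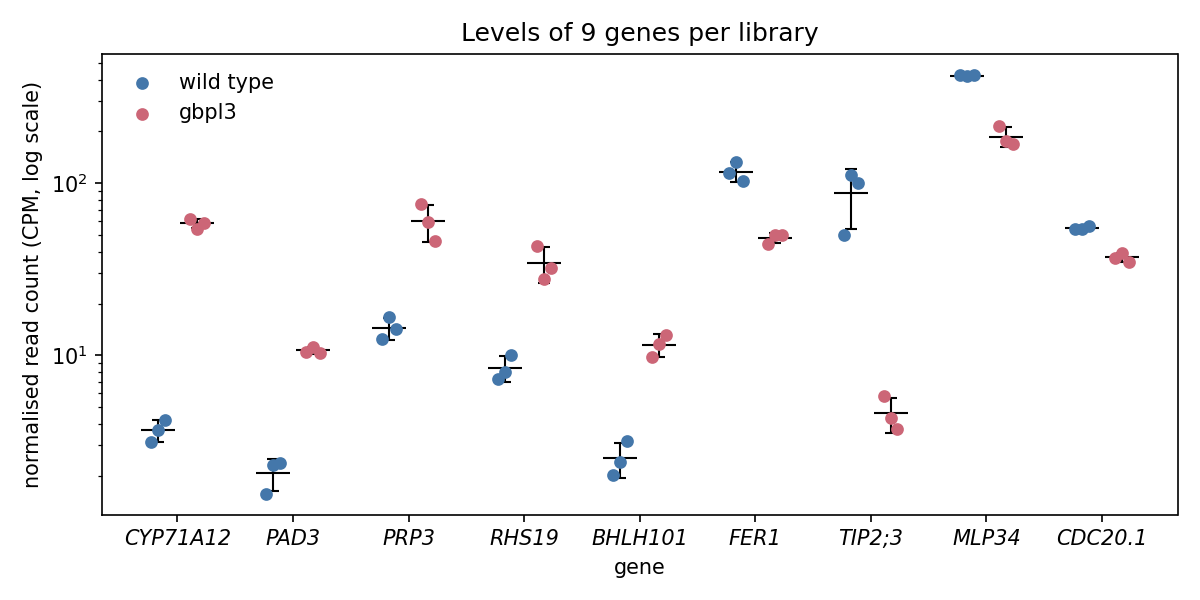
Normalised read counts (CPM, log axis) of named genes in each of 3 wild-type and 3 gbpl3 libraries, with points for libraries, horizontal bars for means and error bars for the SD. CYP71A12, PAD3, PRP3, RHS19 and BHLH101 are higher and FER1, TIP2;3, MLP34 and CDC20.1 lower in gbpl3, with no overlap between the genotypes.

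Of the photosynthesis genes, 15 of 38 were up, none down and 23 not called, with a median log2 fold change of 0.33. LHCB4.2, a light-harvesting protein gene of photosystem II, rose from 1208 ± 239 to 1958 ± 248 CPM and PSBR, a photosystem II subunit gene, from 2908 ± 266 to 4149 ± 484 CPM. LHCB2.1 and LHCB2.2 rose 1.55-fold and 1.52-fold, and near-identical copies of this family can share reads. The camera adjusted p was 6.14e-09, and adjusted p = 0.367 with an estimated correlation, and 27 members were up and 1 down when adjusted over the list alone. Members called higher numbered 22 without wild-type replicate 2 and 23 without gbpl3 replicate 2, but 8 without wild-type replicate 1 and 4 without wild-type replicate 3, gbpl3 replicate 1 or gbpl3 replicate 3. None of LHCB4.2, LHCB2.1, LHCB2.2 and PSBR was called by limma on FPKM values, with highest adjusted p-values of 0.0859, 0.12, 0.109 and 0.208.

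Ribosome biogenesis genes were lower, with 11 of 18 down and none up. FIB2, which encodes the nucleolar methyltransferase fibrillarin, fell 1.60-fold, and PUM24, a ribosomal RNA processing gene, from 44.6 ± 2.29 to 30.0 ± 2.98 CPM. NOP5-1 and NAP57, which belong to small nucleolar ribonucleoproteins, fell 1.47-fold and 1.45-fold. The median was -0.47 (camera adjusted p = 1.9e-09, and adjusted p = 0.223 with an estimated correlation), and 15 members were down when adjusted over the list alone. Without wild-type replicate 1, 6 members were called, and without gbpl3 replicate 3, 4, where the NAP57 call ended (adjusted p = 0.0505). Of the mitotic cell cycle genes 3 of 20 were down and none up: CYC1BAT (also called CYCB1;2) fell 1.62-fold, and CDC20.1 and CDC20.2, activators of the anaphase-promoting complex, 1.48-fold and 1.90-fold. That list's median was -0.32 (camera adjusted p = 1.46e-05, and adjusted p = 0.223 with an estimated correlation), with 5 down when adjusted over the list alone and 7 called without wild-type replicate 2. In the DNA replication list the origin licensing gene CDT1A fell 1.55-fold, 1 of 15 members also when adjusted over the list alone, and its call ended without gbpl3 replicate 3 (adjusted p = 0.109). The list median was -0.18 (camera adjusted p = 0.0125, and adjusted p = 0.223 with an estimated correlation), and 2 members were called without wild-type replicate 2.

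Nuclear pore complex genes had a median of -0.21, with 2 of 30 down and 1 up, as also when adjusted over the list alone. EMB3012 (GP210), which anchors the pore in the membrane, fell from 100 ± 7.72 to 71.5 ± 11.5 CPM, EMB2766 (NUP62), a channel nucleoporin, fell 1.39-fold and NUP98B rose 1.96-fold. NUA, a protein of the nuclear basket, stood at 122 ± 5.15 and 99.9 ± 11.0 CPM (adjusted p = 0.0922). The camera adjusted p was 0.00318, and adjusted p = 0.367 with an estimated correlation. Both falls ended without gbpl3 replicate 3 (adjusted p = 0.103 and 0.17), and that of EMB2766 also without wild-type replicate 1 (0.125), wild-type replicate 3 (0.0692) or gbpl3 replicate 1 (0.0938). Without wild-type replicate 2 or gbpl3 replicate 2, 4 members were lower. EMB2766, with 2040 counts, overlaps AT2G45010 on the same strand, with 1120, and its level is uncertain. None of 18 nuclear lamina and envelope genes was called, also when adjusted over the list alone, and that list was not shifted (median -0.02, camera adjusted p = 0.662).

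Glucosinolate genes went both ways, 4 up and 2 down of 23: CYP79B3, which starts indole glucosinolate synthesis, fell from 96.5 ± 4.13 to 49.7 ± 3.17 CPM, and the myrosinase gene TGG2 rose from 88.9 ± 4.78 to 135 ± 5.32 CPM (list median 0.02, camera adjusted p = 0.722, with 6 up and 3 down when adjusted over the list alone). Without wild-type replicate 3, gbpl3 replicate 1 or gbpl3 replicate 3, 1 member was up, and without gbpl3 replicate 2, 2. The other lists were not shifted. Heat shock and protein folding had 1 member down of 12 (median -0.09, camera adjusted p = 0.463), which was DREB2A, and flavonoid and anthocyanin 1 down of 12 (median -0.12, 0.463), which was MYB12. The DNA damage response had 1 up of 15, GMI1, flowering time 1 up of 14, RAV2, and DNA methylation and silencing 1 down of 14, MET1 (camera adjusted p = 0.54, 0.7 and 0.282). Of the circadian clock genes, none of 9 morning genes was called and 1 of 11 afternoon and evening genes, PRR5, was down (camera adjusted p = 0.935 and 0.76). The MYB12 call ended without wild-type replicate 1 (adjusted p = 0.135) or any gbpl3 replicate (0.0685, 0.0867 and 0.0514), and the PRR5 call without wild-type replicate 3 (0.0861), gbpl3 replicate 1 (0.134) or gbpl3 replicate 3 (0.0859). The MET1 call held only without gbpl3 replicate 2 (adjusted p = 0.0534 to 0.225 in the others). The single members of these lists were named after their values were seen. Adjusted over the list alone, counts in these lists were 1 down for heat shock, 1 up and 1 down for flavonoids, 1 up for DNA damage, 1 up for flowering, 0 for the morning genes and 1 down for the evening genes, and 0 for DNA methylation. Camera's direction was upward against a negative median for the DNA damage, flowering and morning clock lists.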

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

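The length and GC offsets were chosen after seeing the data. GBPL3 kept its direction and its adjusted p under 0.05 in all 16 gene-level alternatives. The counts of genes higher and lower stayed within 1.5 times under RLE and upper-quartile scaling, DESeq2, both count filters and the offsets, and DESeq2 shared 1939 of its 2108 calls with edgeR. Limma on log2(FPKM + 1) with a mean of at least 1 FPKM called 424 genes higher and 390 lower, 189 of them at least 2-fold higher. With log2(FPKM + 0.1) it called 384 and 368, with 202 at least 2-fold higher, and with log2(FPKM + 1) and no filter 294 and 227, with 164 at least 2-fold higher and 93 at least 2-fold lower. In the simulation limma on FPKM also recovered fewer 2-fold changes, 58% against 72%. The simulation left out the TMM factors and changed few genes, so it cannot say how much of the difference in calls this explains. Leaving out 1 library each gave 629 to 1443 genes higher and 320 to 1238 lower. With the replicate number as a block 618 genes were lower and 916 higher. Same-numbered libraries did not deviate together (correlations of deviations -0.0461, -0.0647 and 0.0355). Only replicate 3 of each genotype correlated best with its own number. Pairing by number was thus not seen, but so few libraries cannot exclude it. Camera with an estimated correlation shifted 0 lists, against 14 with the preset correlation and 7 by fry. Of 86 called named genes, calls ended for 1 under DESeq2 and 14 without gbpl3 replicate 3. In the 2 filtered FPKM fits calls ended for 24 and 25 of 82 genes with a value, and in the unfiltered fit for 39 of 86. None turned direction. Among lists, the direction of the list test turned in 15 cases, all in lists not shifted in any setting. The list median did not always change sign with it. Without a count filter the heat shock median was 0.17, and without a filter on FPKM it was 0.0168. The evening clock median was -0.0288, -0.0306 and -0.0288 in the FPKM fits in the order given. Leaving out 1 library each, medians ran from -0.0503 to 0.0956 for the evening clock, -0.370 to 0.199 for flavonoids, -0.0458 to 0.0977 for glucosinolates, -0.128 to 0.0595 for flowering and -0.144 to 0.162 for the morning clock. The cause of these differences between settings was not tested. Depth limits genes near the floor, 0.232 to 0.315 CPM per library.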

Other observations

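The family tests and those of the seed, root hair, length, abundance and GBPL3 region explanations were chosen or reworded after results were seen, whereas the splits, the neighbour test and the fits without 1 library each were set before. Among 181 families that share an annotated product name, genes named as peroxidase superfamily proteins, which include the alpha-dioxygenase gene DOX1, had 17 members higher and 7 lower of 49, and the rises exceeded the share among all named products (Fisher's exact test, one-sided, adjusted p = 1.01e-06 over 362 tests). AT4G36430 rose from 2.64 ± 1.62 to 94.5 ± 8.08 CPM and PRX52 from 0.47 ± 0.424 to 13.3 ± 1.03 CPM, while AT3G01190 fell from 130 ± 16.3 to 39.1 ± 3.43 CPM (n = 3 per genotype, edgeR). Without wild-type replicate 1 the log2 fold changes of AT4G36430 and PRX52, 5.16 and 4.77, were 5.79 and 5.81. Proline-rich extensin-like genes, which encode wall glycoproteins, had 7 higher and 2 lower of 10 (adjusted p = 3.34e-05), led by EXT10, from 4.91 ± 0.893 to 53.0 ± 11.9 CPM, and EXT12, from 4.11 ± 0.699 to 33.1 ± 6.51 CPM. Berberine bridge-like oxidases had 8 higher and 0 lower of 19 (adjusted p = 0.000546), and polyketide cyclase and lipid transport proteins 10 higher and 0 lower of 23 (3.34e-05). Cysteine-rich secretory (CAP) proteins had 5 higher and 1 lower of 11 (0.0162), and aspartyl proteases 10 higher and 2 lower of 48 (0.0286). Lipid transfer and 2S albumin-like proteins went both ways, 14 lower and 8 higher of 55 (median -0.06, adjusted p = 3.34e-05 for falls and 0.3 for rises), among them AT4G12545, from 60.1 ± 7.46 to 14.9 ± 2.54 CPM. The L7Ae family of ribosomal proteins had 7 lower and 0 higher of 11 (3.34e-05). Leaving out 1 library each, 14 to 18 peroxidases, 6 to 8 extensin-like genes, 6 to 9 berberine bridge-like oxidases, 6 to 10 polyketide cyclase proteins, 3 to 5 CAP proteins and 4 to 8 aspartyl proteases were higher. In the same fits 9 to 15 lipid transfer proteins were lower, but L7Ae members called lower numbered 0 without gbpl3 replicate 3 and 2 to 8 in the others. Fisher's exact test treats the members of a family as independent genes, and no family was tested with a correlation among members, whereas camera shifted 0 of the 25 lists once that correlation was estimated. Extensins and other repeats of near-identical sequence can share reads, so counts of single family members are uncertain.

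The genes higher (1253), lower (969), at least 2-fold higher (425) and at least 2-fold lower (147) were counted again in all 10 splits of the 6 libraries. For each of these counts 1 split, the real one, gave as many, and the highest of the others was 0. For lists, 1 split gave 14, and the highest other split 13. With 10 splits no share under 0.05 can be reached. In all splits but the real one, each group holds libraries of both genotypes. Genotype differences then add to the spread within groups, so few gene calls could arise there. Part of the genotype difference also stays between the groups, so the 13 lists do not measure chance alone.

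Seed storage genes differed strongly among gbpl3 libraries: in replicates 1 to 3 the ratio of CRU3 to CRA1 counts was 0.00725, 0.847 and 0.508, and that of SESA1 to SESA5 together to CRA1 was 0.116, 0.577 and 0.0722. Each pair of libraries differed in 1 of these ratios by at least 7.997-fold (counting interval 6.16 to 10.4), which argues against 1 source of seed RNA with a fixed profile as the whole cause. Among members that passed the count filter, the median was 3.93, 3.18 and 3.02 without gbpl3 replicates 1, 2 and 3. With all libraries, the filter left out genes with reads in too few of them, such as CRU3 with 1, 383 and 704 counts in gbpl3. A rise carried by a single gbpl3 library would thus hardly be seen, and these medians cannot decide that question. Camera called the list only with the preset correlation (adjusted p = 0.223 with an estimated correlation). The SESA2 log2 fold change, 3.42 with all libraries, was 8.31 without wild-type replicate 2 and 1.99 without gbpl3 replicate 2, and its call ended without gbpl3 replicate 2 (adjusted p = 0.281), wild-type replicate 3 (0.0987) or gbpl3 replicate 3 (0.0553). Seed-like material that differs between samples and an effect of the genotype stay open and may both contribute.

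Of the root hair genes 7 of 16 were higher and none lower, while root tissue markers had a median log2 fold change of -0.17 (SD 0.71), below the root hair median of 0.82 by more than that spread, which argues against a larger share of root tissue. More hair cells, and a change of expression within hair cells, cannot be told apart: log2 fold changes ran from -0.31 to 3.93 and 0 members were called lower, and genes also expressed in other tissues may rise less than genes of hair cells alone.

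The ribosome biogenesis median was -0.47 both before and after gene length and GC content were removed by offsets per library, and that of photosynthesis 0.33 before and 0.32 after, both beyond the SD of the members (0.18 and 0.19), which argues against such bias as the whole cause of either. The nuclear pore median moved from -0.21 to -0.17 and camera with the preset correlation still called the list (adjusted p = 0.0171), although without offsets the adjusted p was 0.367 with an estimated correlation and 0.116 by fry. The length and GC trends that the offsets model thus account for only part of that median. The remaining -0.17 lies within the SD of the members, 0.28. These SDs describe the spread between genes and not the error of a median, so they cannot decide whether a list shifted. Without offsets, 27 nuclear pore members had negative and 3 had positive log2 fold changes. The call of this list rests on the preset correlation. Whether the genotype lowers that list therefore stays open. In raw count shares, the 10 most abundant genes of each library shift all other genes by -0.0331 on the log2 scale. That is small against the fall of ribosome biogenesis genes, with a median of -0.47. This median is from TMM-scaled counts, however, and TMM is meant to remove such a shift. The comparison of raw shares therefore has little bearing on the fall. No biological explanation of the fall was tested.

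Neighbouring genes tended to be called in the same direction. Of 16623 adjacent pairs that do not overlap and differ in product name, 154 were called in the same direction, against a mean of 97.7 in 10000 shuffles (permutation test, one-sided, 1.58 times as many, p = 0.0001, the smallest the shuffles can give), 109 of them both higher. Pairs called in opposite directions numbered 77, against a mean of 94.6. Related neighbours with differing product names, shared control regions and reads that run on into the next gene may all contribute, and these were not separated. No comparison with another mutant was made, so this may be a general property of seedling transcriptomes.

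Within 1 Mb of GBPL3, 46 of 376 genes were called (12.2%), against 10.7% elsewhere (Fisher's exact test, one-sided, p = 0.195). The odds ratio was 1.16 with a 95% interval of 0.831 to 1.59, so a modest excess near the locus cannot be told apart from none. The gene just upstream, AT5G46060, fell from 2.06 ± 0.805 to 0.433 ± 0.39 CPM (log2 fold change -2.22, edgeR adjusted p = 0.0382), at levels of 0 to 8 counts per gbpl3 library. That call ended without any library but wild-type replicate 1 (adjusted p = 0.0573 to 0.146). It is read from the same strand as GBPL3.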
